A study of Homo sapiens with 27 samples.

How the data were processed

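RNA sequencing counts of 27 libraries of THP-1 cells were analysed. Per the labels, the cells were made into macrophages with 50 nM (30.9 ng/ml) PMA for 48 h, then kept untreated or exposed to LPS (10 pg/ml) with IFNγ (20 ng/ml), or to IL-4 and IL-13 (20 ng/ml each), for 24, 48 or 72 h. RNA was extracted with a column kit, and libraries were made with the sequencing provider's RNA kit. The protocol names IL-4 where the series text names IL14, and the protocol was followed. Per the submitters' processing notes, reads were checked with FastQC 0.11.7, trimmed with cutadapt 4.4, aligned to GRCh38 with HISAT2 and counted per gene with featureCounts. The versions of the last 2 tools, the annotation release, the strandedness and the settings are not given in the sources used here.

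The deposited raw table holds counts for 61541 genes, of which 39556 had a count in any library. The deposited normalized table holds a signal that is the raw count divided by 1 size factor per library, computed by the authors, for 15163 genes with 99.8% of the reads. The ratio of the 2 tables was constant within each column, and how the genes of the second table were chosen is not given in the sources used here. The raw counts were used throughout, and the size factors of the second table served as an alternative. Library totals ran from 17710772 to 27333339 counts with a median of 20313503. Gene symbols came from a table of gene names (42427 with a symbol, 382 more from GENCODE 29), and positions and gene types from the GENCODE 29 annotation of GRCh38. Raw reads were not used here.

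Each library was assigned to 1 of 9 groups of treatment and hour with 3 libraries each. All 27 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with quasi-likelihood tests, TMM scaling and the default expression filter with a minimum count of 10, which left 18059 genes, and the common biological coefficient of variation was 0.127. Contrasts set each treatment against the untreated group of the same hour, the 2 treatments against each other at each hour, the response at 72 h against that at 24 h, and untreated macrophages at 48 and 72 h against 24 h. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 per contrast, and genes called at least 2-fold also had a log2 fold change of at least 1. The standard error of a log2 fold change is its size divided by the square root of F. Adjusted p-values of single genes are those of edgeR. Folds against a group with 0 counts are lower bounds from a floor of 3 counts over the group, and folds against a group with 1 to 3 counts are ratios with a 95% interval. Bounds and intervals cover counting error only. Changes of treatment are relative to TMM scaling.

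The 22 gene lists were written before the data were examined, as were the contrasts, the tests, the alternatives except those named as later and the rule for naming genes. They cover type I interferon-stimulated genes, MHC class I and class II genes, NF-kB inflammatory genes, STAT6 targets, macrophage differentiation, myeloid progenitors, markers of other cell types, cell cycle, cholesterol synthesis, LXR and lipid handling, glycolysis and hypoxia, respiratory chain, lysosome, DNA methylation and histone enzymes, matrix remodelling, complement and coagulation, inflammasome, pattern recognition receptors, stress, and mitochondrially encoded transcripts, and 1 list and some named genes are not reported here. Of their 575 genes 574 were matched, CTGF not. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists and contrasts of a family, and adjusted p-values of lists are those of limma. Where such a call was lost with an estimated correlation, that adjusted p is printed beside it. Medians of lists leave genes at a counting bound at their fitted value unless both values are given.

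Genes named in the text followed a fixed rule. It took the 8 largest rises and falls at 24 h for each treatment and 5 for the 2 treatments against each other, among called genes with at least 5 CPM in the higher group and no overlap between libraries. It added the 3 members of each list with the smallest adjusted p, the 5 largest differences in each direction between hours, the 5 most persistent changes in each direction, and 24 genes fixed by name, of which CCL17 had too few counts to be tested. This gave 189 genes.

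Alternatives were DESeq2 1.42.0, RLE size factors, the deposited size factors, no filter (39556 genes), a strict filter at a mean of 5 CPM (10916 genes), a replicate block, a fit of the compared groups alone, and each library left out in turn. For lists they were an estimated correlation, fry and the block. After the data were seen, total-count scaling and fits without 2 groups of libraries were added, the latter for lists too, and list tests without LPS + IFNγ 24 h replicate 2. The first group is the pair labelled IL-4 + IL-13 24 h replicate 3 and 72 h replicate 3. The second is the 3 libraries with traces of the other cocktail: IL-4 + IL-13 72 h replicate 1, IL-4 + IL-13 24 h replicate 3 and LPS + IFNγ 72 h replicate 3. Replicate numbers did not pair the libraries of different groups. Principal components used log2 CPM with a prior count of 2. Distances between libraries are the median, over 11021 genes with a mean count of at least 100, of the squared difference divided by its Poisson variance, rescaled by the median of a chi-square with 1 degree of freedom so that counting error alone gives 1. Traces were measured on genes of at least 20 CPM in 1 cocktail and at least 100 times lower in the clean 24 and 48 h libraries of the other, and 3 such rules were tried, the last one chosen after seeing the data.

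The tests were checked on simulated data with changes planted in unchanged counts. In each set 67 genes were changed 1.5-fold, 67 by 2-fold and 66 by 4-fold, and 17859 were not. Far more genes were called in the real contrasts with the cocktails, so these figures measure neither recovery nor scaling there. For LPS + IFNγ against untreated at 24 h edgeR recovered 34.3% of genes changed 1.5-fold, 65.7% at 2-fold and 86.4% at 4-fold, with 2 false calls. For the difference between hours it recovered 14.9%, 49.3% and 72.7% with 3 false calls for LPS + IFNγ, and 11.9%, 50.8% and 66.7% with 2 for IL-4 + IL-13. DESeq2 recovered 41.8%, 74.6% and 86.4% for LPS + IFNγ at 24 h with 10 false calls. Camera recovered 1 of 1 planted set with 0 false among 19, on genes drawn independently, so this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.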

Results

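The series holds RNA sequencing of THP-1 cells, a human monocytic leukaemia line, that were made into macrophages with 50 nM phorbol 12-myristate 13-acetate (PMA) for 48 h. The macrophages were then left in fresh medium (untreated), exposed to bacterial lipopolysaccharide (LPS, 10 pg/ml) with interferon gamma (IFNγ, 20 ng/ml), or exposed to interleukins IL-4 and IL-13 (20 ng/ml each). LPS with IFNγ is the classical inflammatory stimulus of macrophages, and IL-4 with IL-13 the alternative one. Each of the 3 treatments was sampled after 24, 48 and 72 h in 3 libraries, which makes 9 groups and 27 libraries. The stated aim of the series is to learn how polarization reprograms macrophages over the long term, so each cocktail was set against the untreated macrophages of the same hour, and the responses of 72 h and 24 h against each other. The libraries held 17710772 to 27333339 counted reads (median 20313503), and 18059 genes had enough counts to be tested. Changes are given as log2 fold changes ± their standard error (SE), medians of gene lists as log2 fold changes alone, and levels as CPM (counts scaled to the size of the library) ± SD, with n = 3 libraries per group throughout.

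In the principal component analysis the LPS + IFNγ libraries lay apart from the rest on the axis with 61.0% of the variance. The share of reads on mitochondrially encoded genes was 2.92% ± 0.241 in untreated macrophages at 24 h and 1.41% ± 0.514 under LPS + IFNγ, with the lowest share, 0.818%, in LPS + IFNγ 24 h replicate 2. That library also detected 28147 genes, against 23552 and 22937 in replicates 1 and 3. The library labelled IL-4 + IL-13 24 h replicate 3 lay nearer to the 72 h replicates 1 and 2 of its treatment (mean distance 4.13, where counting error alone gives 1) than to its own replicates (33.5). The library labelled IL-4 + IL-13 72 h replicate 3 lay nearer to the 48 h libraries (3.21) than to its own replicates (11.4). Both were kept as labelled, and values without this pair are given for some results. Small amounts of the other cocktail's transcripts were present in some libraries, and 3 of these, called the libraries with traces, were left out together in an alternative fit. Their median was 1.79% of the 72 h LPS + IFNγ level in IL-4 + IL-13 72 h replicate 1 and 0.412% in IL-4 + IL-13 24 h replicate 3. On the same genes untreated libraries held 0.0904% to 0.229%, and the 24 h LPS + IFNγ libraries 45.7% to 46.9%. In LPS + IFNγ 72 h replicate 3 the median was 4.28% of the 72 h IL-4 + IL-13 level. It was 0.441% and 0.246% in replicates 1 and 2, which were kept. Untreated libraries held 1.125% to 3.131% on the same 12 genes, so these genes are not absent without IL-4 + IL-13. The labels do not say that the replicates were separate cultures, so every p-value below measures the spread between libraries, which may be technical.

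**Figure D1:**
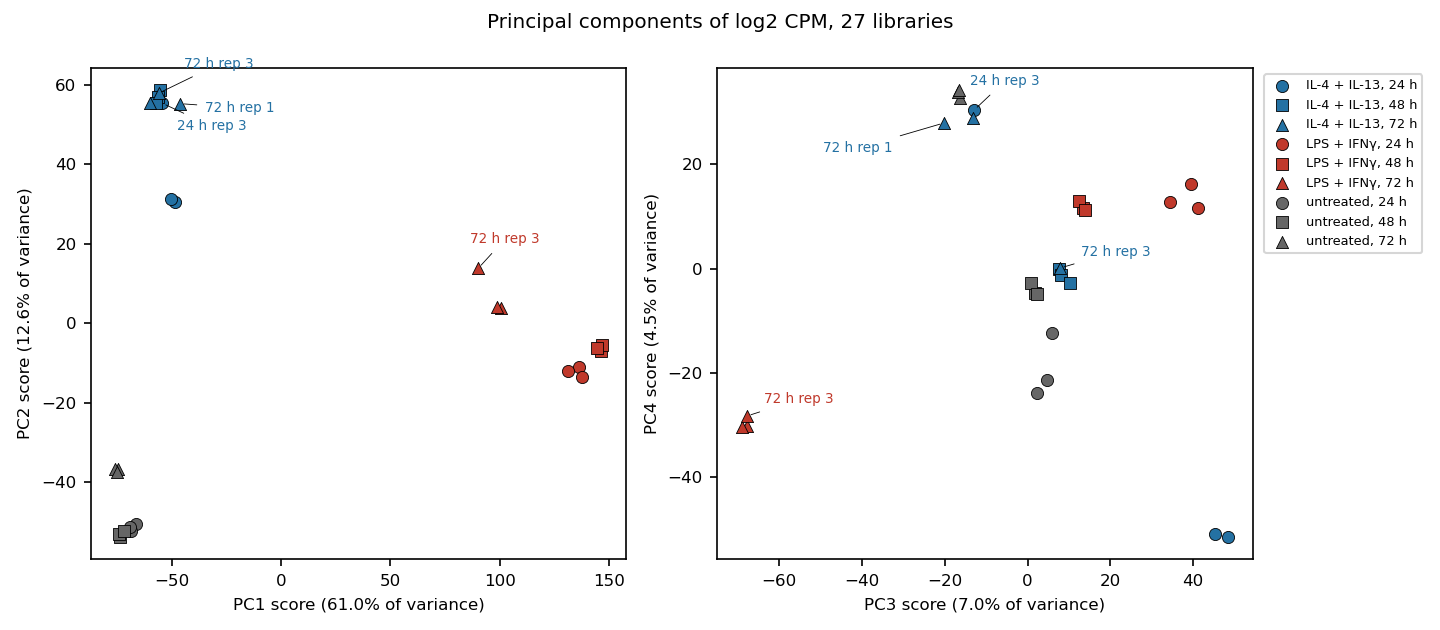
Principal components of the 27 libraries from log2 CPM, the share of variance on each axis in percent, with colours for the treatment and marker shapes for the hour. Component 1 (61.0%) parts LPS + IFNγ libraries from the others, and the library labelled IL-4 + IL-13 24 h replicate 3 lies apart from its own replicates.

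After 24 h of LPS + IFNγ, MHC class I and NF-kB inflammatory genes were higher than in untreated macrophages, as were CXCL9, IDO1 and ACOD1, while TOP2A was lower. CXCL9, a chemokine that draws T cells (ENSG00000138755, chromosome 4, 76001275 to 76007488, GRCh38), held 1 read in the 3 untreated libraries together and stood at 2111 ± 491 CPM after treatment, 139600-fold higher (95% interval 25050 to 5513000). IDO1, which breaks down tryptophan (ENSG00000131203, chromosome 8, 39902275 to 39928444), reached 1423 ± 20.8 CPM and was 93670-fold higher (95% interval 16810 to 3700000). ACOD1, the enzyme that makes itaconate (ENSG00000102794, chromosome 13, 76948497 to 76958642), was not counted in untreated macrophages and reached 50.2 ± 11.4 CPM, at least 1098-fold higher. TOP2A, a topoisomerase of dividing cells (ENSG00000131747, chromosome 17, 40388516 to 40417950), fell from 265 ± 3.35 to 0.978 ± 0.151 CPM, a log2 fold change of -8.06 ± 0.23 (adjusted p = 1.19e-18). Of the 18059 genes, 12000 changed, 6002 upward and 5998 downward, and 6523 of them by at least 2-fold.

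At 24 h of LPS + IFNγ the transcription factor IRF1 rose by 5.33 ± 0.11, the T cell inhibitory ligand CD274 by 9.99 ± 0.25 and the guanylate-binding protein GBP1 by 6.92 ± 0.38. Of the 33 type I interferon-stimulated genes, 31 rose and 1 fell (median 2.81, adjusted p = 1.16e-13, adjusted p = 0.108 with an estimated correlation), with IRF7 up by 3.24 ± 0.12 and PARP9 by 3.13 ± 0.13. The chemokine CXCL10 rose by 9.75 ± 1.33 (adjusted p = 7.16e-07). All 17 MHC class I antigen processing genes rose (median 1.77, adjusted p = 3.82e-13, adjusted p = 0.0263 with an estimated correlation). The peptide transporter TAP1 was 26.9-fold higher, with a log2 fold change of 4.75 ± 0.10. All 15 MHC class II genes rose (median 4.81, adjusted p = 3.11e-09, adjusted p = 0.0900 with an estimated correlation), and their master regulator CIITA rose by 6.17 ± 0.25 and the antigen-presenting chain HLA-DRA by 8.65 ± 0.68. Of the 37 NF-kB inflammatory genes, 35 rose and 0 fell (median 4.97, 4.55 with genes at their bound, adjusted p = 4.95e-14, adjusted p = 0.0447 with an estimated correlation). The cytokine TNF rose by 4.97 ± 0.25, IL1B by 7.64 ± 0.92, the neutrophil chemokine CXCL8 by 9.26 ± 0.80, the monocyte chemokine CCL2 by 5.09 ± 0.59 and the T cell costimulators CD40 and CD80 by 3.31 ± 0.08 and 5.08 ± 0.49. IL6 was at least 104-fold higher. Adjusted over the list alone, the number that rose was 31, 17, 15 and 36 in the order of these lists.

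All 33 cell cycle genes fell (median -5.27, adjusted p = 1.23e-16, adjusted p = 0.109 with an estimated correlation). The mitotic activator CDC20 changed by -7.95 ± 0.19 and the mitotic cyclin CCNB1 by -5.41 ± 0.15, and the kinesin KIF20A was 894-fold lower (95% interval 247 to 7386). Of the 17 myeloid progenitor genes, 2 rose and 14 fell (median -2.17, adjusted p = 0.00132, adjusted p = 0.170 with an estimated correlation). The progenitor transcription factor MYB changed by -6.57 ± 0.38, and CEBPE, a regulator of granulocyte maturation, rose by 3.42 ± 0.16. Of the 13 mitochondrially encoded transcripts, 11 fell (median -0.63, adjusted p = 0.0108, adjusted p = 0.673 with an estimated correlation), with MT-CO3 changed by -1.22 ± 0.20. Replicate 2, the library with the lowest mitochondrial share, carries part of this: without it 9 fell (median -0.33, adjusted p = 0.0138). Of the 28 glycolysis and hypoxia genes, 16 rose and 6 fell (median 0.54, adjusted p = 0.0120, adjusted p = 0.197 with an estimated correlation), and hexokinase HK2 rose by 4.36 ± 0.09 and the angiogenic factor VEGFA by 4.31 ± 0.23. Of the 18 inflammasome genes, 12 rose and 5 fell (median 0.76, adjusted p = 0.0316, adjusted p = 0.367 with an estimated correlation), with the DNA sensor AIM2 up by 8.07 ± 0.35 and the cytokine IL18 at -2.23 ± 0.15. Of the 21 complement and coagulation genes, 15 rose and 5 fell (median 0.96, adjusted p = 0.00951, adjusted p = 0.174 with an estimated correlation), with the protease C1S up by 9.82 ± 0.32 (10.60 without untreated 24 h replicate 1) and properdin (CFP) at -3.96 ± 0.22. Of the 26 endoplasmic reticulum and heat stress genes, 16 rose and 10 fell (median 1.00, adjusted p = 0.0484, adjusted p = 0.692 with an estimated correlation), not called without replicate 2 (adjusted p = 0.0752), and the stress factors ATF3 and DDIT3 rose by 4.12 ± 0.13 and 2.84 ± 0.13. Of the 28 matrix remodelling genes 16 rose and 8 fell (median 1.10, adjusted p = 0.0495, adjusted p = 0.234 with an estimated correlation), with the collagen chain COL6A1 at 2.80 ± 0.11. Adjusted over the list alone, the numbers that rose and fell were 0 and 33 for cell cycle, 2 and 14 for progenitor, 0 and 11 for mitochondrial, 16 and 6 for glycolysis, 12 and 5 for inflammasome, 15 and 5 for complement, 16 and 10 for stress and 17 and 8 for matrix genes.

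Other lists held members that moved both ways and did not pass the list test at 24 h of LPS + IFNγ with all libraries. Of the 34 IL-4 and IL-13 (STAT6) targets, 10 rose and 11 fell (adjusted p = 0.946, tested as lower, with a median of 0.02 and a mean of 0.52). The low-affinity IgE receptor FCER2 rose by 5.0 ± 0.20, the cross-linking enzyme TGM2 by 6.62 ± 0.50 and the lectin CD209 by 2.64 ± 0.21, while the lipoxygenase ALOX15 changed by -3.40 ± 0.58 and the mannose receptor MRC1 by -6.37 ± 0.51. Of the 26 macrophage differentiation and scavenger genes, 15 rose and 8 fell (adjusted p = 0.103), with the chitinase CHIT1 at 5.92 ± 0.23 and the oxidized lipoprotein receptor OLR1 at -3.98 ± 0.16. In cholesterol synthesis 10 of 23 genes rose and 3 fell (adjusted p = 0.263). In LXR and lipid handling 11 of 23 rose and 7 fell (adjusted p = 0.236). In the respiratory chain 7 of 30 rose and 13 fell (adjusted p = 0.255). Of the 26 lysosome genes 13 rose and 6 fell (adjusted p = 0.0533, and 0.0477 without replicate 2). Of the 22 Toll-like and pattern recognition receptor genes 12 rose and 9 fell (adjusted p = 0.336), with TLR2 at 1.36 ± 0.08 and the DNA-sensing adaptor STING1 at -3.87 ± 0.17. Of the 10 measured markers of other cell types, 2 rose and 5 fell (adjusted p = 0.619), and PECAM1, which endothelium and monocytes share, rose by 1.05 ± 0.14. The numbers that rose and fell, adjusted over the list alone, were 10 and 11 for STAT6 targets, 15 and 8 for differentiation, 10 and 3 for cholesterol, 11 and 7 for LXR, 7 and 13 for respiratory chain, 13 and 6 for lysosome, 12 and 9 for receptor and 2 and 5 for other cell type genes. Scaling by total counts in place of TMM moved the median log2 fold change of all genes by -0.42 at 24 h, and 3856 genes rose and 8966 fell, against 6002 and 5998 under TMM, so the balance of rises and falls is relative to the scaling.

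The response of MHC class I and NF-kB inflammatory genes to LPS + IFNγ was still present at 48 and 72 h. CXCL10 rose by 12.10 ± 1.42 at 48 h and 14.35 ± 1.51 at 72 h. TNF rose by 6.41 ± 0.27 and 7.85 ± 0.29, and CCL2 by 5.50 ± 0.67 and 9.63 ± 0.68. CXCL9 stood at 4169 ± 132 and 9557 ± 396 CPM, IDO1 at 3858 ± 136 and 4528 ± 146 CPM, and ACOD1 at 202 ± 21 and 482 ± 17.8 CPM. Against these, TOP2A changed by -6.30 ± 0.20 and -3.66 ± 0.17, and CDC20 by -7.29 ± 0.18 and -2.75 ± 0.14. At 48 h 12461 genes changed (6157 upward, 6304 downward, 7090 by at least 2-fold), and at 72 h 11310 (5669 upward, 5641 downward, 5836 by at least 2-fold).

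At 72 h all 33 type I interferon-stimulated genes rose (median 3.84, adjusted p = 1.48e-21, adjusted p = 0.0447 with an estimated correlation). MHC class I genes rose in all 17 cases (median 2.20, adjusted p = 2.86e-15, adjusted p = 0.0220 with an estimated correlation), and so did all 15 MHC class II genes (median 5.69, adjusted p = 6.8e-11, adjusted p = 0.0732 with an estimated correlation). Of the 37 NF-kB inflammatory genes 36 rose and 0 fell (median 5.75, adjusted p = 7.3e-18, adjusted p = 0.0250 with an estimated correlation). The 4 lists gave 33, 17, 15 and 36 risen members at 48 h, and the same numbers adjusted over the list alone at 48 h and at 72 h. All 33 cell cycle genes were still lower at 72 h (median -3.07, adjusted p = 1.28e-19, adjusted p = 0.0863 with an estimated correlation). Of the 23 cholesterol synthesis genes, 19 rose and 0 fell at 72 h (median 0.79, adjusted p = 9.91e-06, adjusted p = 0.233 with an estimated correlation), with the feedback regulator INSIG1 up by 1.95 ± 0.12 and the synthase HMGCS1 by 1.18 ± 0.09. In glycolysis and hypoxia 25 of 28 genes rose and 0 fell (median 0.96, adjusted p = 6.17e-09, adjusted p = 0.0220 with an estimated correlation). In the lysosome 18 of 26 rose and 2 fell (median 0.66, adjusted p = 0.000606, adjusted p = 0.595 with an estimated correlation). Of the 13 mitochondrially encoded transcripts 12 fell at 48 h and 0 at 72 h (adjusted p = 0.0174 and 0.678, and adjusted p = 0.679 at 48 h with an estimated correlation). Of the 17 myeloid progenitor genes 14 fell at 48 h (median -1.65, adjusted p = 0.00416, adjusted p = 0.226 with an estimated correlation). At 72 h 8 fell (median -1.09, adjusted p = 0.0851). Under total-count scaling 3731 genes rose and 9884 fell at 48 h and 3001 genes rose and 9683 fell at 72 h, with the median of all genes moved by -0.52 and -0.49.

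Genes that changed the same way at 24, 48 and 72 h of LPS + IFNγ answer which parts of the response lasted. Among those with the largest rises were CXCL9, IDO1, ACOD1, the long noncoding RNA SIMALR and the hyaluronan-binding protein TNFAIP6, and SIMALR was at least 736-fold higher at 24 h and at least 513-fold higher at 72 h. Among those with the largest falls were the kinase PDK4, which restrains glucose oxidation, at -6.11 ± 0.33, -7.38 ± 0.44 and -5.66 ± 0.42 for the 3 hours, and the neuropeptide receptor VIPR1 at -5.54 ± 0.45, -5.24 ± 0.46 and -5.36 ± 0.47. Without 1 library PDK4 stood at -6.63 (without LPS + IFNγ 48 h replicate 1), -8.73 (48 h replicate 3) and -6.42 (72 h replicate 3), and VIPR1 at -6.35 (24 h replicate 2). In all, 3842 genes rose and 3536 fell at each of the 3 hours. This balance is relative to the scaling, since under total-count scaling 3001 genes rose and 9683 fell at 72 h alone. Of the genes that rose at 24 h, 4040 (67.3%) also rose at 72 h, against 1884 for independent sets, and of those that fell 3783 (63.1%) also fell, against 1874. The calls of different hours come from different libraries but from 1 fit.

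**Figure D2:**
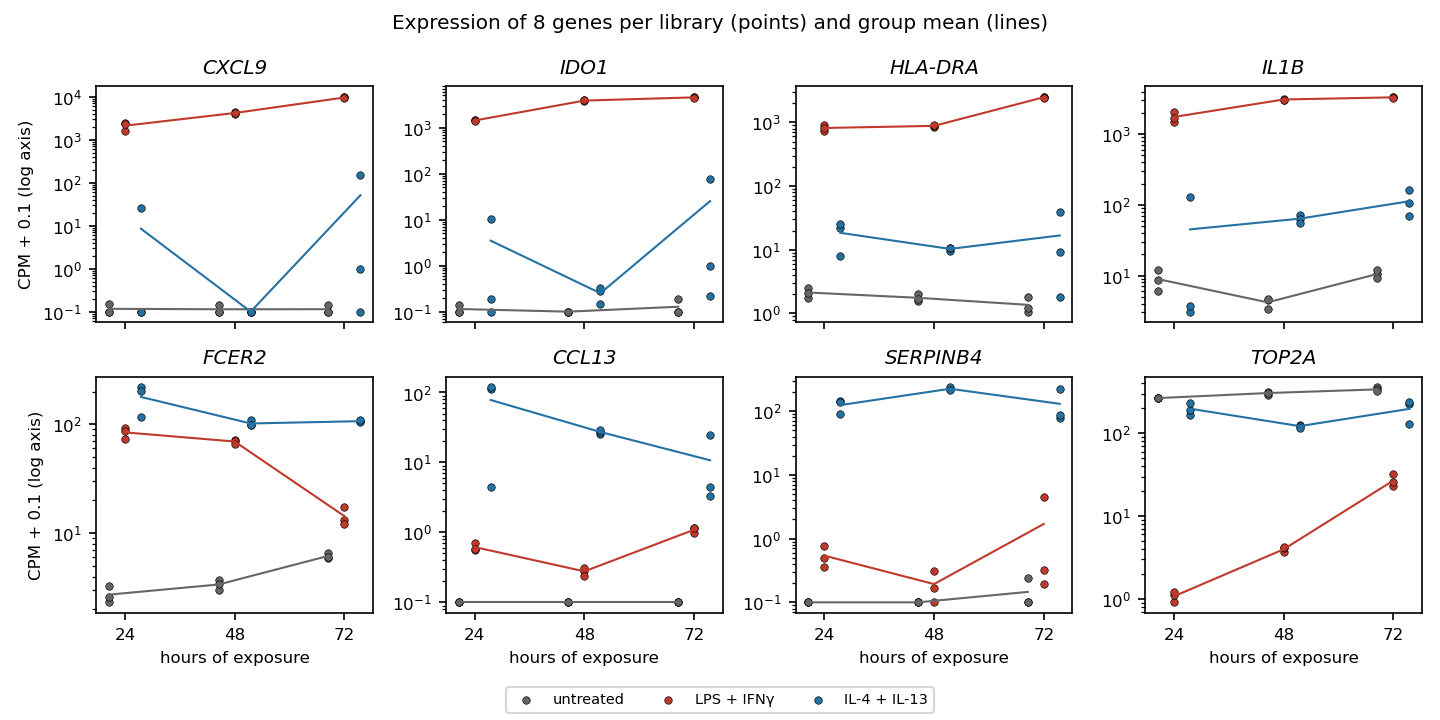
Expression of 8 genes as CPM + 0.1 on a log axis against hours of exposure, with points for single libraries, lines for group means and colours for the treatment. CXCL9 and IDO1 rise by several orders of magnitude under LPS + IFNγ, CCL13 and SERPINB4 under IL-4 + IL-13, and single IL-4 + IL-13 libraries at 24 and 72 h carry CXCL9 and IDO1 above their replicates.

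After 24 h of IL-4 + IL-13 matrix genes were higher than in untreated macrophages, as were CCL13, SERPINB4 and FCER1A, while MYB was lower. Targets of the transcription factor STAT6 were higher too (adjusted p = 0.0760 with an estimated correlation). The monocyte and eosinophil chemokine CCL13 (ENSG00000181374, chromosome 17, 34356452 to 34358610, GRCh38) was not counted in untreated libraries and reached 78.0 ± 63.8 CPM, at least 1822-fold higher. The protease inhibitor SERPINB4 (ENSG00000206073, chromosome 18, 63637259 to 63644298) was also not counted in untreated libraries and was at least 2785-fold higher. The alpha chain of the high-affinity IgE receptor, FCER1A (ENSG00000179639, chromosome 1, 159289714 to 159308224), reached 180 ± 83.7 CPM and was 12320-fold higher (95% interval 2211 to 486700). MYB, a transcription factor of progenitors, changed by -4.06 ± 0.30 (adjusted p = 1.65e-10). Of the 18059 genes 5307 changed, 2947 upward and 2360 downward, and 1823 by at least 2-fold. Without the pair of libraries whose profiles sat with other hours 7350 (3631 upward and 3719 downward) changed. With only the 2 compared groups in the fit 1917 genes changed.

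Of the 34 STAT6 targets 26 rose and 1 fell (median 2.98, adjusted p = 3.82e-13, adjusted p = 0.0760 with an estimated correlation). The IgE receptor FCER2 rose by 6.09 ± 0.21, the signalling inhibitor CISH by 6.29 ± 0.32, and the protease inhibitor SPINT2 by 6.76 ± 0.32. The transglutaminase TGM2 rose by 7.05 ± 0.51, the lipoxygenase ALOX15 by 4.05 ± 0.38, the lectin CD209 by 3.95 ± 0.23 and the mannose receptor MRC1 by 0.86 ± 0.29. CISH rose by 6.95 without untreated 24 h replicate 3, and MRC1 was not called without that library (0.68), IL-4 + IL-13 24 h replicate 1 (0.72) or replicate 2 (0.67). The chemokine CCL22 rose by 2.14 ± 0.35. The chemokine CCL17 had too few counts to be tested. CD163, a haemoglobin scavenger receptor, stood at 0.30 ± 0.20 (adjusted p = 0.299). Of the 28 matrix remodelling genes 16 rose and 3 fell (median 0.76, adjusted p = 3.82e-05, adjusted p = 0.0263 with an estimated correlation). The collagen chains COL6A1 and COL6A2 rose by 2.84 ± 0.11 and 2.58 ± 0.10 and the elastase MMP12 by 6.01 ± 0.42 (5.36 without the library labelled 24 h replicate 3). Of the 33 cell cycle genes 23 fell (median -0.49, adjusted p = 6.66e-13, adjusted p = 0.174 with an estimated correlation), with the replicative helicase subunit MCM4 at -0.97 ± 0.10 and TOP2A at -0.42 ± 0.15, and 32 fell without the pair. Of the 17 progenitor genes 8 fell (median -0.62, adjusted p = 3.63e-05, adjusted p = 0.0755 with an estimated correlation). Of the 18 inflammasome genes 11 fell (median -0.44, adjusted p = 0.000140, adjusted p = 0.108 with an estimated correlation), with the sensor NLRP1 at -1.72 ± 0.22 and IL18 at -1.54 ± 0.14. Of the 28 glycolysis and hypoxia genes 13 rose and 4 fell (median 0.24, adjusted p = 0.00147, adjusted p = 0.108 with an estimated correlation), and phosphofructokinase PFKP rose by 3.13 ± 0.18. Of the 26 lysosome genes 14 rose and 2 fell (median 0.34, adjusted p = 0.00442, adjusted p = 0.679 with an estimated correlation), and 21 rose without the pair, the cholesterol transporter NPC1 by 1.75 ± 0.12 in the labelled groups. Rises and falls adjusted over the list alone were 27 and 2 for STAT6 targets, 16 and 3 for matrix, 0 and 25 for cell cycle, 0 and 8 for progenitor, 1 and 12 for inflammasome, 13 and 5 for glycolysis and 14 and 2 for lysosome genes.

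Some genes of the LPS + IFNγ response also rose under IL-4 + IL-13 at 24 h. Among these the cytokine signalling inhibitor SOCS1 rose by 6.92 ± 0.21, CD274 by 5.42 ± 0.26 and the adhesion molecule ICAM1 by 2.63 ± 0.15. The chemokines CCL5 and CCL2 rose by 4.72 ± 0.28 and 5.53 ± 0.58, while of the 37 NF-kB inflammatory genes 11 rose and 4 fell (adjusted p = 0.277). IL1B rose by 2.34 ± 0.77 (adjusted p = 0.0247), which rests on the library labelled IL-4 + IL-13 24 h replicate 3. Without the pair the change was -1.40 (adjusted p = 6.3e-05), and without that library alone -1.40. Without untreated 24 h replicate 2 or 3, at 2.32 and 2.11, it was not called. Of the 15 MHC class II genes 4 rose (adjusted p = 0.0875) and 10 without the pair (adjusted p = 0.00289), with CIITA up by 2.19 ± 0.27 and HLA-DRA by 3.18 ± 0.62. Of the 33 type I interferon-stimulated genes 5 rose (adjusted p = 0.337) and 13 without the pair (adjusted p = 0.0172). Of the 23 LXR and lipid handling genes 10 rose and 1 fell (median 0.29, adjusted p = 0.010, adjusted p = 0.477 with an estimated correlation), with the lipogenic regulator SREBF1 up by 2.03 ± 0.12. Of the 30 respiratory chain genes 8 rose and 1 fell (median 0.12, adjusted p = 0.0152, adjusted p = 0.326 with an estimated correlation). Without the pair the adjusted p was 0.0906, and this median lies within the shift of -0.14 that total-count scaling gave all genes, so its direction depends on the scaling. Of the 26 stress genes 12 rose and 3 fell (median 0.25, adjusted p = 0.0292, adjusted p = 0.684 with an estimated correlation). When adjusted over the list alone, the numbers up and down were 11 and 5 for NF-kB, 6 and 0 for MHC class II, 1 and 0 for type I interferon, 11 and 1 for LXR, 8 and 1 for respiratory chain and 12 and 3 for stress genes.

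At 24 h of IL-4 + IL-13 the list test was not passed by MHC class I genes (4 of 17 rose and 4 fell, adjusted p = 0.624) or by cholesterol synthesis (5 of 23 rose and 5 fell, adjusted p = 0.75). Complement and coagulation genes did not pass it (7 of 21 rose and 3 fell, adjusted p = 0.543). Nor was it passed by macrophage differentiation genes (7 of 26 rose and 7 fell, adjusted p = 0.751) or pattern recognition receptors (3 of 22 rose and 4 fell, adjusted p = 0.459). Mitochondrially encoded transcripts (0 of 13 rose and 0 fell, adjusted p = 0.139, and 0.00762 without LPS + IFNγ 24 h replicate 2) did not pass it either with all libraries, and neither did markers of other cell types (2 of 10 rose and 2 fell, adjusted p = 0.915). Adjusted over the list alone, the numbers that rose and fell were 6 and 4, 5 and 6, 8 and 3, 8 and 8, 3 and 4, 0 and 0 and 2 and 2 in the same order. Total-count scaling moved the median of all genes by -0.14, -0.12 and -0.12 at 24, 48 and 72 h. Under it 1991 genes rose and 4107 fell at 24 h, 2863 genes rose and 4663 fell at 48 h and 2419 genes rose and 4377 fell at 72 h.

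At 48 and 72 h of IL-4 + IL-13 the genes FCER2, CISH, MRC1, TGM2, F13A1 and FCER1A were higher than in untreated macrophages. FCER2 rose by 4.95 ± 0.20 at 48 h and 4.13 ± 0.18 at 72 h, and CISH by 6.53 ± 0.33 and 6.54 ± 0.33. MRC1 rose by 1.83 ± 0.31 and 2.10 ± 0.32, and TGM2 by 6.35 ± 0.50 and 5.58 ± 0.48 (4.95 without the library labelled 72 h replicate 3). The coagulation factor subunit F13A1 rose by 5.53 ± 0.61 and 7.18 ± 0.71. FCER1A was at least 3625-fold higher at 48 h and 7823-fold higher (95% interval 1404 to 309000) at 72 h. At 48 h 7384 genes changed (3955 upward, 3429 downward, 2381 by at least 2-fold), and at 72 h 6479 (3426 upward, 3053 downward, 1901 by at least 2-fold).

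Of the 34 STAT6 targets 22 rose and 4 fell at 48 h (median 2.96, 2.64 with genes at their bound, adjusted p = 4.52e-07, adjusted p = 0.175 with an estimated correlation). By 72 h 20 rose and 5 fell (median 2.19, adjusted p = 6.52e-06, adjusted p = 0.175 with an estimated correlation). Of the 28 matrix genes 17 rose and 2 fell at 72 h (median 0.84, adjusted p = 2.24e-06, adjusted p = 0.0220 with an estimated correlation). Of the 23 cholesterol synthesis genes 20 rose at 48 h (median 0.60, adjusted p = 1.49e-08, adjusted p = 0.138 with an estimated correlation). At 72 h 12 rose (median 0.51, adjusted p = 7.77e-05, adjusted p = 0.297 with an estimated correlation). Of the 30 respiratory chain and citrate cycle genes 21 rose at 48 h (median 0.32, adjusted p = 3.58e-07, adjusted p = 0.0499 with an estimated correlation). At 72 h 18 of them rose (median 0.25, adjusted p = 7.57e-07, adjusted p = 0.0575 with an estimated correlation). The complex III subunit UQCRC1 rose by 0.94 ± 0.07 and 0.87 ± 0.07. Of the 28 glycolysis genes 20 rose and 4 fell at 72 h (median 0.48, adjusted p = 3.75e-07, adjusted p = 0.0250 with an estimated correlation). Of the 33 cell cycle genes 24 fell at 48 h and 25 at 72 h (median -0.70, adjusted p = 3.44e-14, adjusted p = 0.155 with an estimated correlation). At 72 h 20 of 37 NF-kB genes rose (median 0.83, adjusted p = 0.000760, adjusted p = 0.373 with an estimated correlation). Without the 3 libraries with traces of the other cocktail 16 rose (adjusted p = 0.0179). TNF stood at 1.34 ± 0.33 and CXCL8 at 2.08 ± 0.67 at 72 h with all libraries, and at 0.57 (adjusted p = 0.0660) and 0.46 (adjusted p = 0.148) without those 3. The same 2 values were 0.57 and 0.47 without IL-4 + IL-13 72 h replicate 1 alone, and CXCL8 was not called without untreated 72 h replicate 2 (1.98) or 3 (2.10) either. Adjusted over the list alone, the numbers that rose and fell at 72 h were 21 and 5 for STAT6 targets, 18 and 2 for matrix, 13 and 0 for cholesterol, 18 and 0 for respiratory chain, 21 and 4 for glycolysis, 0 and 27 for cell cycle and 22 and 1 for NF-kB genes.

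A lasting response to IL-4 + IL-13 was also measured by the genes that changed the same way at all 3 hours. The largest rises among them were those of FCER1A, SERPINB4, CCL13, SERPINB3 and the keratin KRT16, and SERPINB3 was at least 174-fold higher, at least 370-fold higher and at least 236-fold higher at 24, 48 and 72 h. The largest falls were those of the matrix protein THBS2 at -3.66 ± 0.26, -4.10 ± 0.26 and -4.98 ± 0.26, the carnitine synthesis enzyme BBOX1, the arginine deiminase PADI2, ARMC9 and MYB. In all 1604 genes rose and 1120 fell at each hour. This balance is relative to the scaling. Under total-count scaling falls outnumbered rises at each single hour, with 1991 up and 4107 down at 24 h. The numbers were 2863 and 4663 at 48 h, and 2419 and 4377 at 72 h. Of the genes that rose at 24 h, 1808 (61.4%) also rose at 72 h, against 559 for independent sets, and of those that fell 1372 (58.1%) also fell, against 399.

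**Figure D3:**
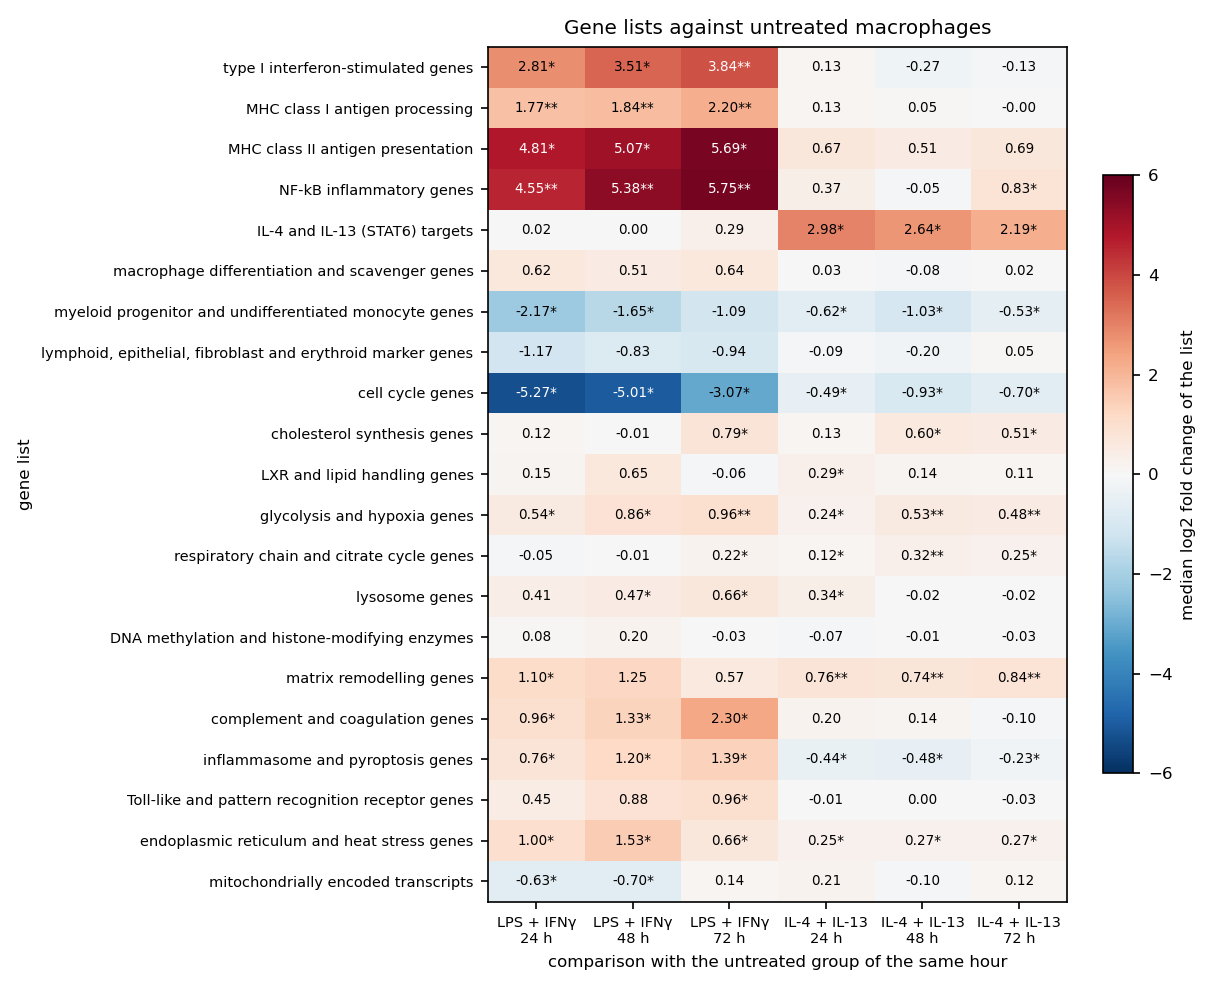
Median log2 fold change of 21 of the 22 gene lists against untreated macrophages of the same hour, with columns for treatment and hour, 1 star for an adjusted p under 0.05 with the preset correlation and 2 stars where the call also held with an estimated correlation. Genes at a counting bound enter these medians at that bound, so some values differ from the fitted medians in the text. Type I interferon, antigen presentation and NF-kB lists are high and cell cycle genes low under LPS + IFNγ, and STAT6 targets are high under IL-4 + IL-13.

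Set directly against each other at 24 h, the cocktails differed in MHC class I and class II genes, which were higher under LPS + IFNγ, and in FCER1A and F13A1, which were higher under IL-4 + IL-13. At 24 h the surface receptor CLEC4E was at least 187-fold higher and the costimulatory ligand CD48 at least 266-fold higher under LPS + IFNγ, TNFAIP6 rose by 10.88 ± 0.40, and SIMALR and the protease inhibitor SERPINB7 were at least 716-fold higher and at least 142-fold higher. In the other direction FCER1A was at least 3866-fold lower and F13A1 stood at -12.31 ± 1.03 (-13.57 without LPS + IFNγ 24 h replicate 2 and -11.71 without replicate 3). The neuropeptide NTS was at least 323-fold lower, the peptide hormone ENHO 2213-fold lower (95% interval 397 to 87450) and the purine receptor P2RY12 1942-fold lower (95% interval 348 to 76750). All 17 MHC class I genes were higher under LPS + IFNγ at 24 h (median 1.84, adjusted p = 6.14e-14, adjusted p = 0.0195 with an estimated correlation). So were all 15 MHC class II genes (median 3.98, adjusted p = 5.0e-11, adjusted p = 0.0491 with an estimated correlation). Of the 34 STAT6 targets 27 were lower and 4 higher (median -2.76, adjusted p = 5.13e-05, adjusted p = 0.271 with an estimated correlation). All 33 cell cycle genes were lower under LPS + IFNγ than under IL-4 + IL-13 (median -4.70, adjusted p = 6.14e-16, adjusted p = 0.0860 with an estimated correlation). Of the 30 respiratory chain genes 20 were lower at 48 h (median -0.31, adjusted p = 0.000225, adjusted p = 0.0996 with an estimated correlation). At 72 h 8 were lower and 7 higher (adjusted p = 0.603). Adjusted over the list alone the 24 h numbers higher and lower were 17 and 0, 15 and 0, 4 and 28 and 0 and 33 for the first 4 lists, and 1 and 20 for the respiratory chain at 48 h and 7 and 8 at 72 h. The test called 11584 genes at 24 h (5606 higher and 5978 lower under LPS + IFNγ), 12223 at 48 h (5898 and 6325) and 10152 at 72 h (4934 and 5218). At least 2-fold were 5985, 6692 and 4831 of them. Total-count scaling moved the median of all genes by -0.27, -0.41 and -0.37 at the 3 hours, and gave 4005 higher and 8032 lower at 24 h, 3856 and 9020 at 48 h, and 2887 and 8874 at 72 h.

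Part of the response was common to both cocktails. TGM2, SOCS1, CD274, CD209, FCER2 and VCAM1 rose under each of them at 24 h, and MYB, GPR34, a receptor for lysophosphatidylserine, and BBOX1 fell under each. At 24, 48 and 72 h 1777, 2133 and 2181 genes rose under both, against 979.5, 1348 and 1075 for independent sets (n1 × n2/N), and 1501, 2039 and 2122 fell under both, against 783.8, 1197 and 953.7. In opposite directions, 434, 699 and 403 rose under LPS + IFNγ and fell under IL-4 + IL-13, and 508, 885 and 358 did the reverse. Both responses were measured against the same untreated libraries, so part of the excess may come from these shared controls. Across the 18059 genes, which are not independent replicates, Pearson's r between the responses was 0.399, 0.341 and 0.470, and Spearman's rho 0.388, 0.351 and 0.479. In 20 simulations of groups without any change, shared controls alone gave a mean r of 0.488, 0.470 and 0.485 and a mean rho of 0.441, 0.431 and 0.440. These arise from noise alone, so they do not give the part of the observed r or rho that comes from shared controls. The simulated covariance was 0.0732, 0.0696 and 0.0717 against the observed 0.764, 0.733 and 0.779 (differences 0.691, 0.663 and 0.707). No gene was called under both there, which follows from simulating no change. The simulations therefore do not show how many of the common calls come from shared controls.

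TGM2 is an example of the shared part: at 24 h it rose by 6.62 ± 0.50 under LPS + IFNγ and 7.05 ± 0.51 under IL-4 + IL-13. SOCS1 rose by 6.02 ± 0.21 and 6.92 ± 0.21. For ALOX15 the changes were -3.40 ± 0.58 and 4.05 ± 0.38, for the glycolytic enzyme PFKP -1.15 ± 0.17 and 3.13 ± 0.18, and for the integrin chain ITGAM -1.12 ± 0.10 and 1.34 ± 0.10.

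The response to LPS + IFNγ differed between 72 h and 24 h for single genes, while none of the 13 lists called for this difference kept its call with an estimated correlation. CDC20 was lower by a log2 fold change of -7.95 ± 0.19 at 24 h and -2.75 ± 0.14 at 72 h, a difference of 5.21 ± 0.23 (adjusted p = 1.09e-13). OASL, an interferon-induced antiviral protein, rose by 4.19 ± 0.21 and 6.57 ± 0.23, a difference of 2.38 ± 0.32, and CCL2 by 4.53 ± 1.18 more at 72 h. ADGRE1, a macrophage surface receptor, went from -2.78 ± 0.43 to 4.19 ± 0.47. The serine synthesis enzymes PHGDH and PSAT1 went from 3.78 ± 0.57 and 4.61 ± 0.55 at 24 h to -0.71 ± 0.54 and -0.17 ± 0.51 at 72 h (adjusted p = 0.262 and 0.787), and the urea cycle enzyme ASS1 from 2.69 ± 0.45 to -2.42 ± 0.46. The difference of F13A1, 8.15 ± 1.78, rests on LPS + IFNγ 72 h replicate 3, since without the 3 libraries with traces it was -0.19 (adjusted p = 0.830), without that library alone -0.18, and without any other LPS + IFNγ library 7.55 to 9.41. The interaction test called 7255 genes, 3927 with a more positive and 3328 with a more negative response at 72 h, and 3272 by at least 2-fold.

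Of the 33 cell cycle genes 27 differed upward (median 2.02, adjusted p = 1.05e-08, adjusted p = 0.428 with an estimated correlation). Of the 33 type I interferon-stimulated genes 25 did so (median 1.10, adjusted p = 7.33e-11, adjusted p = 0.428 with an estimated correlation). Of the 17 progenitor genes 9 differed upward and 2 downward (median 1.67, adjusted p = 0.0149, adjusted p = 0.428 with an estimated correlation). Of the 13 mitochondrially encoded transcripts 11 differed upward (median 0.81, adjusted p = 0.00297, adjusted p = 0.663 with an estimated correlation), and 10 did without LPS + IFNγ 24 h replicate 2 (median 0.57, adjusted p = 0.000766). Of the 30 respiratory chain genes 15 differed upward and 2 downward (median 0.36, adjusted p = 0.000219, adjusted p = 0.428 with an estimated correlation). Of the 23 cholesterol synthesis genes 15 differed upward (median 0.53, adjusted p = 0.000503, adjusted p = 0.517 with an estimated correlation). The numbers that rose and fell, adjusted over the list alone, were 31 and 0, 25 and 0, 9 and 2, 12 and 0, 15 and 2 and 17 and 0 in the same order.

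Fewer genes differed between the hours, as labelled, in the response to IL-4 + IL-13. PHGDH, PSAT1 and ASS1 rose at 24 h by 3.45 ± 0.56, 2.69 ± 0.51 and 2.29 ± 0.44 and stood at -0.84 ± 0.54, -0.84 ± 0.52 and -1.47 ± 0.43 at 72 h. The differences were -4.29 ± 0.77, -3.53 ± 0.73 and -3.76 ± 0.62 (-4.94, -4.28 and -4.48 without the pair). With the compared groups alone in the fit the 24 h rises of the 3 genes and the differences of PHGDH and PSAT1 were not called. The inflammatory calcium-binding protein S100A8 went from -0.52 ± 0.40 to 3.2 ± 0.60, a difference of 3.72 ± 0.73. S100A8 fell in untreated macrophages between these hours, so the difference does not by itself show a late rise under IL-4 + IL-13. Without the pair S100A8 stood at 2.31 at 72 h and the difference at 2.37, without the library labelled 72 h replicate 3 alone at 2.31 and 2.83, and the difference was not called with the compared groups alone. The lipogenic regulator SREBF1 differed by -1.26 ± 0.16. The interaction test called 1625 genes (854 upward and 771 downward, 458 by at least 2-fold). Of the 23 cholesterol synthesis genes 10 differed upward (median 0.44, adjusted p = 1.18e-05, adjusted p = 0.428 with an estimated correlation). Of the 26 lysosome genes 5 differed downward (median -0.21, adjusted p = 0.0132, adjusted p = 0.80 with an estimated correlation), and 22 did without the pair. Rises and falls adjusted over the list alone were 11 and 0 and 1 and 7. The count rests on the library labelled IL-4 + IL-13 24 h replicate 3. It was 4435 without that library, 5236 without the pair, 3994 without the 3 libraries with traces, and 433 with the compared groups alone in the fit.

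Untreated macrophages also changed between 24 and 72 h in fresh medium. Each difference between these hours in the response to a cocktail contains this change with the opposite sign. Both cocktails share these untreated libraries, so their differences are not independent. The complement component C1QC changed by -5.09 ± 0.62, the calcium-binding proteins S100A8 and S100A12 by -4.78 ± 0.56 and -4.95 ± 0.57, and the scavenger receptor COLEC12 by -4.11 ± 0.60. The collagenase MMP1 rose by 4.2 ± 0.89, the lysyl oxidase LOXL4 by 3.92 ± 0.50 and the thrombin receptor F2R by 3.88 ± 0.80. Of the 33 cell cycle genes 11 rose and 3 fell (median 0.33, adjusted p = 0.00283, adjusted p = 0.981 with an estimated correlation). Of the 26 stress genes 2 rose and 14 fell (median -0.51, adjusted p = 0.000124, adjusted p = 0.928 with an estimated correlation). Of the 26 lysosome genes 8 fell (median -0.28, adjusted p = 0.0402, adjusted p = 0.981 with an estimated correlation). Of the 13 mitochondrially encoded transcripts 3 fell (median -0.47, adjusted p = 0.0382, adjusted p = 0.981 with an estimated correlation). When adjusted over the list alone, the numbers up and down were 11 and 3, 2 and 15, 1 and 10 and 1 and 9. Between 48 and 24 h 1018 genes changed (458 upward and 560 downward, 132 by at least 2-fold), and between 72 and 24 h 4366 (2171 and 2195, 1043 by at least 2-fold). The first count was 2818 and the second 6619 with the compared groups alone in the fit, and 3131 and 6591 without the pair. The first was 2428 without the 3 libraries with traces and 389 to 871 when each library was left out in turn, with more than a 1.5-fold change in 5 of 6 such fits.

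Enzymes of DNA methylation and histone modification were followed because the series title names methylation, which was not analysed here. DNMT1, which maintains methylation at replication, changed by -0.21 ± 0.05, -0.17 ± 0.05 and -0.12 ± 0.05 at 24, 48 and 72 h of LPS + IFNγ, and by 0.61 ± 0.05, 0.80 ± 0.05 and 0.50 ± 0.05 under IL-4 + IL-13. Its partner UHRF1 changed by -3.96 ± 0.12, -3.04 ± 0.12 and -2.33 ± 0.11 under LPS + IFNγ, and by -1.06 ± 0.10, -0.29 ± 0.10 and -0.96 ± 0.10 under IL-4 + IL-13. The de novo methyltransferase DNMT3A changed by -0.33 ± 0.08, -0.65 ± 0.08 and -0.79 ± 0.08 and DNMT3B by -1.54 ± 0.23, -1.73 ± 0.24 and -1.75 ± 0.23 under LPS + IFNγ. The demethylating dioxygenase TET2 stood at -0.01 ± 0.09, 0.33 ± 0.09 and 0.53 ± 0.09 under LPS + IFNγ, the 48 h value turning to -0.20 under total-count scaling, and the 72 h value, 0.04 under that scaling, losing its call. Under IL-4 + IL-13 TET2 changed by -0.37 ± 0.09, -0.24 ± 0.09 and -0.26 ± 0.09. Small changes among these lost their call when single libraries were left out. DNMT1 at 72 h of LPS + IFNγ lost it in 5 of 6 such fits (-0.11 to -0.13) and UHRF1 at 48 h of IL-4 + IL-13 in 4 (-0.27 to -0.28). TET2 lost it under IL-4 + IL-13 in all 6 at 48 h (-0.20 to -0.27) and in 4 at 72 h (-0.23 to -0.26). The 24 h change of TET2 was not called with the compared groups alone. The methyltransferase SMYD3 changed by -5.48 ± 0.18 at 24 h of LPS + IFNγ. Of the 29 measured enzymes 11 rose and 12 fell at 24 h of LPS + IFNγ (adjusted p = 0.932, tested as lower, with a median of 0.08 and a mean of -0.22) and 3 rose and 5 fell at 24 h of IL-4 + IL-13 (adjusted p = 0.229). Adjusted over the list alone the numbers were 11 and 12 and 3 and 5.

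**Figure D4:**
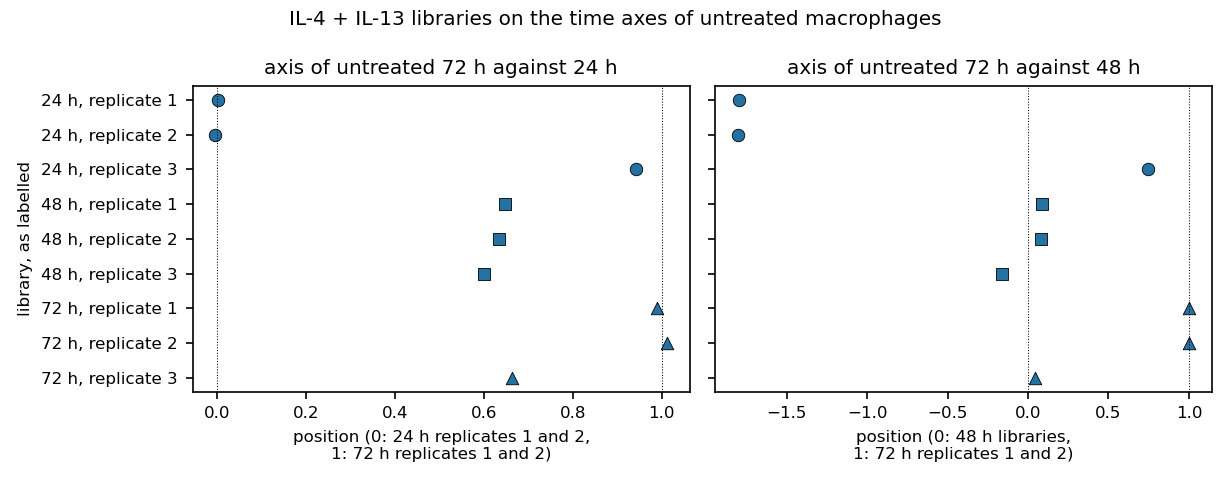
Positions of the 9 IL-4 + IL-13 libraries, named as labelled, on axes weighted by the change of untreated macrophages from 24 to 72 h (left, 0 at the 24 h replicates 1 and 2) and from 48 to 72 h (right, 0 at the 48 h libraries), with 1 at the 72 h replicates 1 and 2. The library labelled 24 h replicate 3 lies at 0.943 on the left axis and 72 h replicate 3 at 0.041 on the right, which restates their distances to the same libraries.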

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

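The tests of a swap between hours, of transcripts carried over from the other cocktail and of a response of the whole group were chosen only after the result was seen, as were the values without the pair of libraries in doubt and without the 3 libraries with traces. Every result in this part other than the 3 patterns at its end stands here because its response at 72 h differed from that at 24 h in the test of the difference itself, with n = 3 libraries per group. That difference also contains the change of untreated macrophages between the hours, as for C1QC, S100A8, S100A12, MMP1 and LOXL4. Both cocktails share the untreated libraries.

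For LPS + IFNγ 7255 genes differed, and 1 of 100 splits drawn at random gave as many, the real one. The splits exchanged the hours within the treated and within the untreated libraries, and the highest of the others gave 6195 genes. A chance assignment of hours to the treated and untreated libraries together was thus excluded at this number of splits. In the 6 splits that kept the treated hours and mixed the untreated ones the count was 5459 to 6195. Splits that mixed the treated hours gave at most 798. Mixing hours widens the spread within the refitted groups, so these counts do not show which libraries the result rests on. The 6 splits are too few to exclude chance for the untreated hours alone.

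Lists that differed for LPS + IFNγ, with the median of the differences over their genes, included cell cycle genes (2.02), cholesterol synthesis genes (0.53), glycolysis and hypoxia genes (0.57), inflammasome and pyroptosis genes (0.52), MHC class I antigen processing (0.33), MHC class II antigen presentation (0.69), mitochondrially encoded transcripts (0.81), myeloid progenitor and undifferentiated monocyte genes (1.67), NF-kB inflammatory genes (0.87), respiratory chain and citrate cycle genes (0.36), Toll-like and pattern recognition receptor genes (0.47) and type I interferon-stimulated genes (1.10). With an estimated correlation between genes none of the 13 lists that differed was called.

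Of the 189 named genes 123 differed for LPS + IFNγ, as log2 response at 72 h minus log2 response at 24 h. The difference was positive for 74 of them, including CXCL13 9.16, F13A1 8.15, ADGRE1 6.97, SPC25 6.63, CALCRL 6.61, GPR34 6.47, ENHO 5.98, KIF20A 5.72, PBK 5.47, C1QC 5.26, NEK2 5.21, CDC20 5.21, STYXL2 4.89, PADI2 4.84, CCL2 4.53, TOP2A 4.41, RGS18 4.19, P2RY12 3.82, S100A12 3.80, RNASE3 3.67, MRC1 3.43, MYB 3.22, S100A8 3.09, CCNB1 2.92, TNF 2.88, SMYD3 2.83, RHEX 2.82, PDE7B 2.57, OASL 2.38, CASP5 2.34, SPINT2 2.30, OLR1 2.29, CDH2 1.95, UHRF1 1.62, SAMD9L 1.61, NOD2 1.54, STING1 1.54, CISH 1.53, HLA-DQB1 1.51, CD33 1.37, GBP1 1.36, CD40 1.26, PFKP 1.21, HMGCS1 1.2, MT-CO3 1.15, CCL5 1.14, TLR2 1.11, MT-ATP6 1.09, PSME2 1.00, SUCLG1 0.96, TAPBP 0.94, MCM3 0.92, CTSH 0.88, PARP9 0.88, HLA-DRB5 0.88, CD163 0.85, MT-ND4L 0.74, IFIH1 0.73, NPC2 0.72, UQCRC2 0.71, MT-ND3 0.71, TNFAIP2 0.64, MDH2 0.62, TAP2 0.60, IRF7 0.59, ICAM1 0.56, MEFV 0.54, TET2 0.54, KDM1A 0.49, TAP1 0.49, IDI1 0.36 and DTX3L 0.36. It was negative for 49: ST6GALNAC3 -6.66, LINC02244 -6.35, CLGN -6.16, ORM1 -6.15, S100P -6.0, C1S -5.43, EHF -5.33, MMP1 -5.24, ASS1 -5.11, LOXL4 -5.06, CHIT1 -4.93, PSAT1 -4.78, PHGDH -4.49, STC2 -4.01, FCER2 -3.79, COL1A1 -3.46, MMP12 -3.28, THBS2 -3.17, PCSK5 -3.09, ARMC9 -2.81, AIM2 -2.55, PFKFB4 -2.33, LPL -2.19, TXNRD1 -2.17, SCD -2.16, COL6A1 -1.76, ATF3 -1.72, PECAM1 -1.57, VEGFA -1.55, TGM2 -1.53, SREBF1 -1.46, COL6A2 -1.39, HK2 -1.35, NDRG1 -1.18, ITGAX -1.04, ATF4 -1.03, NLRP1 -0.96, PTGS1 -0.93, ITGAM -0.91, CD209 -0.89, PROS1 -0.71, NQO1 -0.64, CSF1R -0.62, MMP19 -0.60, NPC1 -0.55, DNMT3A -0.46, UQCRC1 -0.35, SCARB2 -0.34 and B2M -0.30. For 12 of these genes (among them CALCRL, CXCL13, EHF, ENHO, GPR34, KIF20A, NEK2, P2RY12, PBK, SPC25 and STYXL2) at least 1 group held 3 counts or fewer, so their fitted size depends on the prior count. Without the pair in doubt 136 of the 189 differed, 123 of them the same genes.

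Leaving out 1 library ended the call of some of these differences for LPS + IFNγ. Among them were CALCRL (4.45 without LPS + IFNγ 72 h 3), CD163 (0.74 without LPS + IFNγ 24 h 3), CISH (0.88 to 1.42 without any of 4 libraries), EHF (-5.33 to -4.70 without any of 9 libraries), F13A1 (-0.18 without LPS + IFNγ 72 h 3), GPR34 (5.19 without LPS + IFNγ 72 h 3), ICAM1 (0.47 to 0.56 without any of 5 libraries), IDI1 (0.29 to 0.31 without untreated 24 h 2, untreated 72 h 3), MMP19 (-0.56 without untreated 24 h 2), MRC1 (2.26 without LPS + IFNγ 72 h 3), NLRP1 (-0.93 to -0.82 without any of 4 libraries), STYXL2 (3.52 without LPS + IFNγ 72 h 3) and TGM2 (-1.53 to -1.28 without any of 10 libraries), with the number of the replicate after its group. Some others kept the call but moved by more than 1.5 times, such as C1S (-6.20 without untreated 24 h 1), CXCL13 (8.40 without untreated 24 h 3), CXCL13 (10.95 without untreated 72 h 1), ENHO (7.89 without LPS + IFNγ 24 h 1), ENHO (4.99 without LPS + IFNγ 72 h 3), P2RY12 (5.72 without LPS + IFNγ 24 h 3), PBK (8.18 without LPS + IFNγ 24 h 1), RGS18 (3.58 without LPS + IFNγ 24 h 3), S100A12 (4.38 without untreated 72 h 1), S100P (-7.05 without LPS + IFNγ 72 h 1), S100P (-5.35 without LPS + IFNγ 72 h 2), SPINT2 (1.68 without LPS + IFNγ 72 h 3) and ST6GALNAC3 (-7.49 without LPS + IFNγ 72 h 2).

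For IL-4 + IL-13 1625 genes differed, and 14 of 100 splits drawn in the same way gave as many, the real one included, so chance was not excluded. The highest other split gave 7324 genes. It put the library labelled 72 h replicate 3 with 24 h replicates 1 and 2, and also reversed the untreated hours. The same treated grouping with the untreated hours as labelled gave 3402, so the excess does not come from the treated grouping alone. A structure of the samples still shows: of the 13 other splits with as many genes, 10 had this treated grouping. Another 2 put a different 72 h library with 24 h replicates 1 and 2. In the 6 splits that kept the treated hours and mixed the untreated ones the count was 0 to 1. The lists that differed, with the median of the differences, were cholesterol synthesis genes (0.44), glycolysis and hypoxia genes (0.20), IL-4 and IL-13 (STAT6) targets (-0.75), LXR and lipid handling genes (-0.16), lysosome genes (-0.21), NF-kB inflammatory genes (0.44), respiratory chain and citrate cycle genes (0.090) and type I interferon-stimulated genes (-0.33), and none of these 8 was called with an estimated correlation.

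Of the 189 named genes 56 differed for IL-4 + IL-13, as log2 response at 72 h minus log2 response at 24 h. The difference was positive for 31 of them, including CXCL13 9.57, RHEX 4.46, S100A12 4.42, CALCRL 4.38, ADGRE1 3.75, S100A8 3.72, PID1 3.01, GPR34 2.39, CASP5 2.36, RGS18 2.21, TNF 2.10, PDE7B 1.73, RNASE3 1.52, THBD 1.46, NOD2 1.02, MEFV 0.84, TNFAIP2 0.73, SQLE 0.65, SMYD3 0.63, CDC20 0.61, INSIG1 0.54, IDI1 0.53, HMGCS1 0.53, TLR2 0.51, NQO1 0.48, HK2 0.44, TAP2 0.27 and MDH2 0.27. It was negative for 25: PHGDH -4.29, C1S -4.10, ST6GALNAC3 -4.02, ASS1 -3.76, PSAT1 -3.53, STC2 -3.34, PCSK5 -3.28, LOXL4 -2.86, FCER2 -1.96, P2RY12 -1.75, PTGS1 -1.69, CCL5 -1.39, CIITA -1.37, THBS2 -1.32, PFKFB4 -1.30, SREBF1 -1.26, ATF3 -1.2, SCD -0.89, ITGAM -0.78, ATF4 -0.72, TAPBP -0.56, ITGAX -0.54, GBP3 -0.54, MCOLN1 -0.45 and SCARB2 -0.30. For CXCL13 and RHEX at least 1 group held 3 counts or fewer. Without the pair in doubt 96 of the 189 differed, and 53 of the 56 were among them, RNASE3, SMYD3 and THBS2 not.

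Leaving out 1 library ended the call of some of these differences for IL-4 + IL-13. Among them were CDC20 (0.53 to 0.62 without any of 9 libraries), CIITA (-1.33 to -1.15 without any of 5 libraries), CXCL13 (5.89 to 8.81 without IL-4 + IL-13 72 h 1, untreated 24 h 3), GBP3 (-0.47 to -0.46 without IL-4 + IL-13 24 h 1 and 2), GPR34 (1.86 to 2.64 without any of 8 libraries), HK2 (0.34 to 0.43 without any of 4 libraries), INSIG1 (0.28 to 0.58 without any of 9 libraries), MCOLN1 (-0.43 to -0.38 without any of 5 libraries), MDH2 (0.21 to 0.29 without any of 10 libraries), NQO1 (0.41 to 0.48 without any of 6 libraries), RGS18 (1.67 to 2.23 without any of 9 libraries), RHEX (3.69 to 4.63 without any of 7 libraries), RNASE3 (1.30 to 1.33 without untreated 24 h 2, untreated 72 h 2), SCARB2 (-0.29 to -0.26 without any of 7 libraries), SCD (-0.91 to -0.74 without any of 8 libraries), SMYD3 (0.52 to 0.68 without any of 7 libraries), SQLE (0.51 to 0.65 without any of 7 libraries), STC2 (-3.25 to -2.91 without any of 5 libraries), TAP2 (0.22 to 0.27 without any of 6 libraries) and THBS2 (-1.35 to -1.11 without any of 8 libraries), with the number of the replicate after its group. Some others kept the call but moved by more than 1.5 times, such as C1S (-4.88 without untreated 24 h 1), CALCRL (3.61 without untreated 24 h 1), LOXL4 (-1.62 without IL-4 + IL-13 24 h 3), PID1 (3.6 without IL-4 + IL-13 24 h 3), S100A12 (3.41 without IL-4 + IL-13 72 h 3), S100A8 (2.83 without IL-4 + IL-13 72 h 3) and TNF (1.33 without IL-4 + IL-13 72 h 1).

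The first pattern weighed is that 2 IL-4 + IL-13 libraries lay with libraries of another hour than their label. A swap of the library labelled 24 h replicate 3 with a 72 h library was argued against, since 0 of the 3 libraries labelled 72 h lay nearest to 24 h replicates 1 and 2. A wrong hour on the label stays open. On the axis of change in untreated macrophages that library lay at 0.943, where 0 is 24 h and 1 is 72 h, and the library labelled 72 h replicate 3 lay at 0.041 between 48 h (0) and 72 h (1). These axes end at the libraries whose distances showed the pattern, so the positions restate it and decide nothing. Cultures that ran ahead of or behind their hour could give the same positions, and this was not tested. No biological explanation is given by the design, since both libraries had the same treatment as their group.

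The second pattern is that LPS + IFNγ 24 h replicate 2 detected 28147 genes, 3008 of them in that library alone, against 82 to 166 in any other. Library size was argued against, since 94.9% of its excess over replicates 1 and 3 was left after thinning all libraries to 17710772 reads. RNA of another cell type was not settled. Among genes under 1 CPM in replicates 1 and 3, the 10 genes with most of the excess held 1.07% of it. Whole libraries here gave their 10 highest genes only 8.48% to 9.84% of reads, so a low share cannot argue against it. Reads of genomic DNA or other background spread over genes may be the source: among genes silent in the other 26 libraries the share detected rose from 2.86% in the shortest 25% of genes to 25.9% in the longest 25%, a ratio of 9.06, where other libraries had ratios of 1.10 to 3.5. No biological explanation was tested.

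The third pattern is the traces of the other cocktail's transcripts, found with a rule that was revised 2 times after its first results were seen. Carry-over of RNA or reads may be the source in 2 of the 3 libraries, where the trace was close to 1 constant share of the other cocktail's level: the slope of log2 trace on log2 level was 0.990 (SE 0.0254, 36 genes) in IL-4 + IL-13 72 h replicate 1 and 1.03 (SE 0.0837, 12 genes) in LPS + IFNγ 72 h replicate 3. In the third, IL-4 + IL-13 24 h replicate 3, it was 0.889 (SE 0.0840, 34 genes), with shares of 0.262% to 0.624% between quartiles. This slope leaves carry-over open there too, but no explanation was tested for that library. The first 2 rules gave 5 and 22 genes for IL-4 + IL-13 72 h replicate 1 with shares of 1.59% and 1.77%, and 1 and 3 genes for LPS + IFNγ 72 h replicate 3 with shares of 4.84% and 3.69%. A response of the whole group would need the other 2 libraries to hold at least 25% of its share. It was argued against for the former of these, where they held at most 9.50% (95% interval 6.18 to 16.3 over resampled genes). For the latter they held at most 10.3%, with an interval of 2.04 to 33.4 over 12 genes that spans the 25%, so it cannot be told apart from carry-over. The first 2 rules gave 0 and 1.91% there, on 1 and 3 genes, but they chose genes by their absence from these same 2 libraries. Untreated libraries held 1.125% to 3.131% on the 12 genes. Some of the 4.28% in LPS + IFNγ 72 h replicate 3 may thus not be transcripts of the other cocktail, which was not tested. Whether any mixing happened between cells, RNA or sequencing indices was not tested either.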

How the results depend on the processing

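Total-count scaling and the fits without the pair in doubt (IL-4 + IL-13 24 h replicate 3 and 72 h replicate 3) or without the 3 libraries with traces, and list tests without LPS + IFNγ 24 h replicate 2, were tests chosen only after the result was seen. The 15 counts of changed genes stayed within 1.5 times their value under DESeq2, RLE size factors, the deposited size factors, no filter, the strict filter, the replicate block and total-count scaling. In 261 of 276 comparisons with an alternative they did so, and 15 moved further. The 13 counts of genes changed at least 2-fold all moved beyond 1.5 times under the strict filter, as did 6 with 1 library left out, and 25 of 220 in all.

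With only the compared groups in the fit 1917 genes changed for IL-4 + IL-13 at 24 h, 433 differed between its hours, and untreated macrophages changed in 2818 genes at 48 h and 6619 at 72 h. Without the pair 5236 genes differed between the hours of IL-4 + IL-13, and untreated macrophages changed in 3131 genes at 48 h and 6591 at 72 h. Without the 3 libraries with traces the first 2 of these were 3994 and 2428. The libraries in doubt enter the pooled spread of every other contrast, and leaving them out or fitting fewer groups changes that spread. Leaving out 1 library gave 1094 to 4435 genes for the difference between hours of IL-4 + IL-13, the highest without IL-4 + IL-13 24 h replicate 3, and 389 to 871 for untreated macrophages at 48 h, where 5 of 6 such counts (389, 412, 426, 470 and 520) lay beyond 1.5 times.

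The correlation between the responses to both cocktails ranged from 0.414 to 0.438 at 24 h, 0.361 to 0.378 at 48 h and 0.482 to 0.488 at 72 h when each untreated library was left out. With all libraries the correlation was 0.399, 0.341 and 0.470, below each of these ranges. It was 0.352 at 24 h and 0.460 at 72 h without the pair, and 0.529 at 72 h under the strict filter, which tests fewer genes. For the others the cause was not tested.

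Of the log2 fold changes of named genes 18704 comparisons gave the same outcome, called or not called, while 376 lost the call, 389 gained it and 4 turned. TET2 at 48 h of LPS + IFNγ went to -0.20 under total-count scaling, which moved the median of all genes by -0.52. IL1B at 24 h of IL-4 + IL-13 went to -1.40 without the pair and without the 3 libraries with traces, and ranged from -1.40 to 2.89 when each library was left out, the lowest without IL-4 + IL-13 24 h replicate 3. All 3 settings leave out that library, so the turn rests on it, and what sets that library apart was not tested. Of the 286 list tests 106 lost the call with an estimated correlation and 9 with fry, which gave 47 more calls. Without the pair 5 lost and 16 gained the call, without the 3 libraries with traces 6 and 13, and with the replicate block 2 lost it. Without LPS + IFNγ 24 h replicate 2 stress genes at 24 h and lysosome genes at 48 h of LPS + IFNγ lost the call (adjusted p = 0.0752 and 0.0526) and 4 lists gained it. Depth limits the smallest genes: 12 of the 123 named differences for LPS + IFNγ involved a group with 3 counts or fewer.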

Other observations

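None of the tests of splits in this part was chosen after the result was seen. For a comparison of 3 against 3 libraries there are 10 splits, so the share of splits with as many genes cannot go under 0.1. For LPS + IFNγ against untreated macrophages 1 of 10 splits, the real one, gave 12000 genes at 24 h, 12461 at 48 h and 11310 at 72 h, and the highest other split gave 0 each time. For IL-4 + IL-13 it was 1 of 10 with 5307, 7384 and 6479 genes, and the highest other splits gave 1986, 1 and 0. For the 2 cocktails against each other it was 1 of 10 with 11584, 12223 and 10152 genes, and the highest others gave 839, 0 and 0. For untreated macrophages it was 1 of 10 with 1018 genes at 48 h and 4366 at 72 h, with 0 for the highest others. Of the genes that changed the same way at all 3 hours, 1 of 100 splits gave as many as the real 7378 for LPS + IFNγ and 1 of 100 as many as the real 2724 for IL-4 + IL-13, with 0 for the highest others. This restates the splits of single hours, since a count over all 3 hours cannot exceed that of its lowest hour, so it does not exclude chance.

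Over 108 pairs of libraries with the same replicate number in different groups, the median correlation of their deviations from the group means was -0.00155, and 8 of 27 libraries correlated best with a library of their own number.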
